A study of Mus musculus with 88 samples.

How the data were processed

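Hearts of dKO mice, without SR-BI and apolipoprotein E, and of HET control mice, with 1 working Scarb1 allele and no apolipoprotein E, were profiled on Affymetrix arrays at ages of 21, 31 and 43 days, on chow or with probucol. Total RNA had been extracted with Trizol and labelled with biotin, per the labels' protocols, and each mouse had its own array, per the study's design text. The deposited values were linear signal intensities for 12488 probe sets on 88 arrays, and MAS5 was the program named in the submitters' processing notes, with no version. The step that put the arrays on a shared scale is not given in the sources used here. A straight line fitted to each array against the first, dKO chow replicate 1 at 21 days, had a slope of 0.975 to 1.07. The median signal of an array ranged from 27.8 to 75.4, so arrays were not equal in brightness. All 12488 values of the first array had at most 1 decimal, against at most 0.969% of the values of any other array. Pairwise correlations between arrays were 0.739 to 0.955, and no pair looked like an array deposited more than once. The number of arrays limits the precision, and no detection calls per probe set were used here.

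Groups came from the genotype, age and diet in the labels. The description of dKO chow replicate 2 at 21 days gives another age than its title, source and age field, which were followed, and the comparisons were repeated without it. Of the probe sets, 11251 were in the platform annotation used, 10855 with 1 gene symbol and 396 with several, and 1193 that are not control probe sets had none there. By Entrez identifier 10839 of them were found in the gene table of the GRCm38 patch 6 assembly, which changed 0 symbols, and 8252 symbols were on the array. No coordinates are given, since the annotation names no build. Signals were raised to a floor of 4.22, the 10th percentile of all values, and converted to log2, with no further scaling. Probe sets in the upper 60% by mean signal with 1 symbol were kept, and the probe set with the highest mean stood for its gene, which left 5672 genes. Differences of genes near the floor are understated, and other probe sets of a gene were compared where they passed the filter.

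A linear model with a mean for each of the 12 groups was fitted to all 88 arrays with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8. All arrays were fitted together, since the small probucol groups then share the estimate of the spread. Moderated tests with an intensity trend were run for 16 contrasts, and p-values were adjusted by Benjamini and Hochberg within each contrast at a threshold of 0.05. The contrasts were genotype on chow at each age, its change from 21 days, age in HET hearts, probucol within each genotype at each age, genotype on probucol, and the difference of the probucol effect between genotypes. Gene lists, 38 in number, covered heart muscle, metabolism, stress, leukocytes and other cell types, and 34 had at least 3 tested members. They were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, and members were also adjusted over the list alone. Some members belong to more than 1 list and many are expressed in several cell types.

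Named genes followed a rule. Scarb1 and Apoe came first. For genotype on chow and for probucol in dKO hearts, the 8 largest rises and the 8 largest falls past the threshold were eligible, with up to 4 members of each list with the smallest p, or 2 where none passed. For the other contrasts it was the 5 largest rises and falls and list members already named. The design, the lists, this rule and most alternatives were set before the data were examined. These alternatives were quantile normalization, median centring, no floor or a floor at the 30th percentile, no filter or the upper 40%, the mean of a gene's probe sets, only the groups compared, the replicate number as a block, no intensity trend, array weights, the ratio of the 3' to the 5' Gapdh control probe set as a covariate, an added minimum of 1.5-fold, and leaving out single replicates of the small groups. The array set as a block, separate fits within the array sets, calls shared by 4 settings, leaving out 6 arrays with a high score on the first residual component, covariates of Eif2s3y minus Xist and of the 3' to 5' actin ratio, and list tests without single HET probucol hearts were added after the data had been seen. The actin ratio differed between groups, with a mean log2 value at 31 days of 0.386 in dKO chow and 0.0354 in dKO probucol hearts, and at 43 days of 0.172 and -0.116.

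The genes that define the 2 array sets were read from the residuals after the group means, whose second component held 6.62% of the variance. A score of 40 genes from each end of that component was taken on quantile-normalized signals with the group means left in. It left a gap between 0.142 and 0.697, with 68 arrays below and 20 above. Group differences can thus enter the score, and the origin of the sets is not given in the sources used here. The first component, with 10.3%, had 6 arrays that scored above 13. The share of the 43-day genotype difference left with probucol was computed on genes at least 2-fold apart. These were chosen with the odd-numbered dKO chow arrays and measured with the even-numbered ones, with an interval from 1000 resamples of arrays. The HET chow arrays were the same in both steps, and the chosen genes were kept fixed over the resamples. Because genotype and probucol comparisons share the dKO chow arrays, 20 simulations with unchanged groups gave the correlation from sharing alone. For each count of genes in groups of at least 3 hearts, 100 splits of the arrays were compared, the real one included.

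The procedure was tested on simulated data, with 200 of 5672 genes changed 2-fold against the spread of the real arrays. It recovered 82.5%, 82.5% and 87.0% of them for genotype on chow at 21, 31 and 43 days, 76.0%, 85.0% and 79.5% for probucol in dKO hearts, and 60.5%, 62.0% and 45.5% for probucol in HET hearts. For the change of the genotype difference from 21 to 43 days it recovered 65.0%, and for the difference of the probucol effect at 43 days 33.5%. False calls made up 1.94% to 9.57% of all calls, and 6 of 11 comparisons exceeded the nominal 5%, most of all probucol in dKO hearts at 31 days. The simulated values varied independently between genes and arrays, without array sets, brightness differences or a floor. These rates need not hold for the real arrays. Left out of the gene tests were the 66 control probe sets, probe sets with several or no symbols, and dim probe sets. A sex covariate from Ddx3y and Xist was not run, since Ddx3y was not among the annotated genes. Sex is not in the labels used here. The sex-linked gene Xist exceeded Eif2s3y in 3 of 3, 1 of 3 and 0 of 2 HET probucol hearts at 21, 31 and 43 days. In HET chow hearts it did so in 5 of 9, 4 of 10 and 4 of 9. By these genes, sex and probucol cannot be fully told apart in HET hearts.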

Results

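RNA from whole hearts of 88 mice, with 1 mouse per array, was measured on Affymetrix expression arrays of 12488 probe sets. The mice called dKO lacked SR-BI, the receptor for high-density lipoprotein encoded by Scarb1, together with apolipoprotein E, the ligand that clears lipoprotein remnants. The control mice, called HET, carried 1 working Scarb1 allele and also lacked apolipoprotein E. Hearts were taken at ages of 21, 31 and 43 days. According to the study's design text, dKO mice on chow had no detectable coronary artery disease at 21 days, small infarcts with heart failure at 31 days and extensive infarcts with severe heart failure at 43 days, while HET mice on chow stayed free of detectable disease. Further mice received a diet with probucol, a lipid-lowering antioxidant drug. On chow there were 10, 10 and 12 dKO hearts and 9, 10 and 9 HET hearts at the successive ages, and on probucol 6, 8 and 6 dKO hearts and 3, 3 and 2 HET hearts. The median signal per array ran from 27.8 to 75.4, and the number of arrays limits the precision. Differences are log2 values with their standard error, and each adjusted p of a gene comes from limma. A list described as shifted with only 1 adjusted p beside it also passed with an estimated correlation between genes.

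Scarb1, the targeted gene, was lower in dKO than in HET hearts at every age on chow. Its mean log2 signal in dKO hearts was 5.90 ± 0.49 (SD, n = 10), 6.68 ± 0.38 (SD, n = 10) and 6.92 ± 0.41 (SD, n = 12) at 21, 31 and 43 days. In HET hearts it was 7.48 ± 0.37 (SD, n = 9), 7.43 ± 0.45 (SD, n = 10) and 7.62 ± 0.24 (SD, n = 9). The differences were -1.58 ± 0.17 (adjusted p = 5.56e-11) at 21 days, -0.75 ± 0.17 (adjusted p = 3.85e-04) at 31 days and -0.69 ± 0.16 (adjusted p = 2.50e-04) at 43 days. Signal remained in dKO hearts, and 23 of 52 dKO arrays lay above the lowest of 36 HET arrays as deposited, against 4 after median centring. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so the gene is a limited check of the labels. On probucol the mean was 6.11 ± 0.38, 6.57 ± 0.28 and 6.39 ± 0.29 in dKO hearts (SD, n = 6, 8 and 6) and 6.92 ± 0.31, 7.61 ± 0.08 and 7.66 ± 0.12 in HET hearts (SD, n = 3, 3 and 2). Apoe, missing in all mice, had 2 probe sets with group means between 2.18 and 3.99, with the floor at 2.08, and was too dim to be tested.

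**Figure D1:**
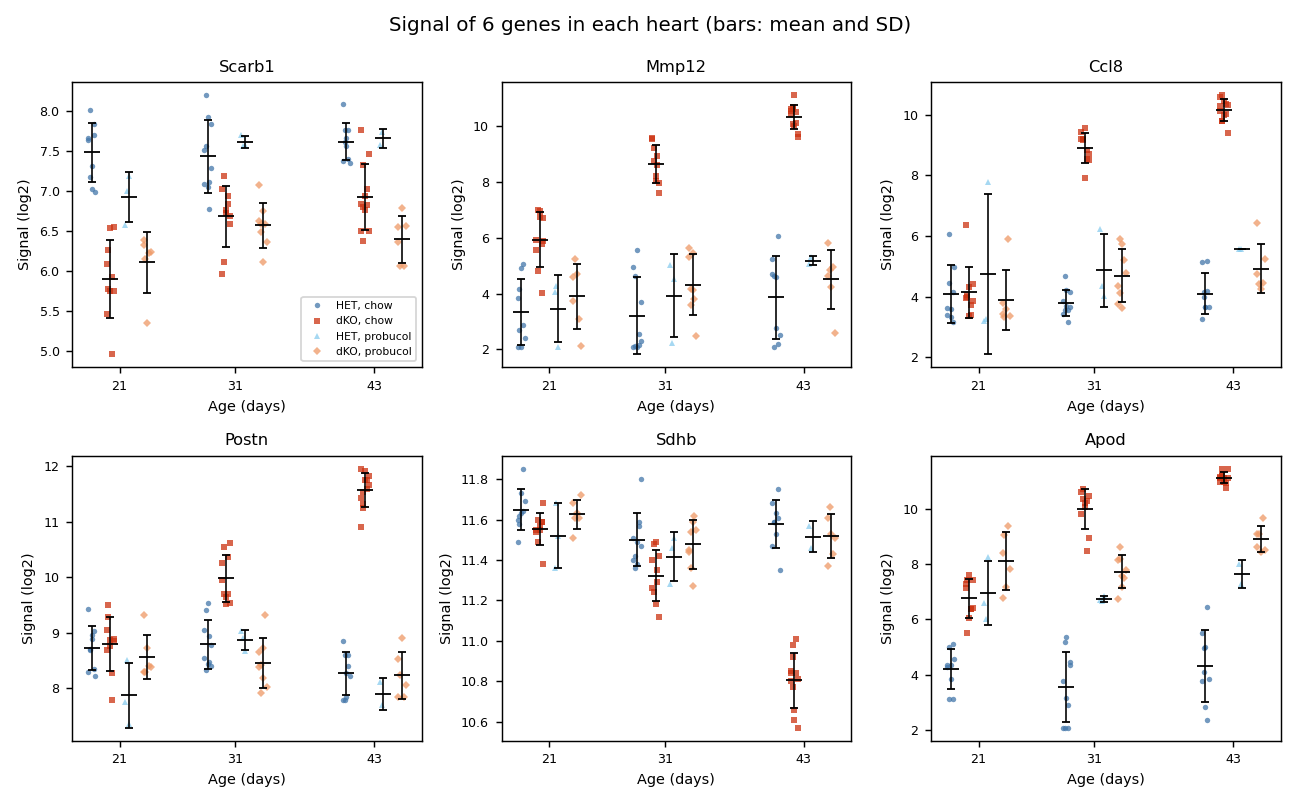
Log2 signal of 6 genes in each heart (vertical axis) against age in days (horizontal axis), with points for mice, bars for mean and SD, and colours for genotype and diet. Mmp12, Ccl8 and Postn are highest in chow-fed dKO hearts at 43 days, and Sdhb is lowest there.

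Arrays differed in brightness along with the groups, so the median gene itself shifted between them. The median log2 difference of all 5672 tested genes between dKO and HET hearts on chow was -0.10, 0.18 and 0.26 at 21, 31 and 43 days, and with probucol in dKO hearts it was 0.05, -0.25 and -0.31. The balance of higher and lower genes therefore depends on the scaling, and counts after median centring are given beside those as deposited. A score from genes of the second component of the residual spread split the arrays into a set of 68 and a set of 20. The smaller set held 6 of 10 dKO and 2 of 9 HET hearts on chow at 21 days, 0 of 10 and 6 of 10 at 31 days, and 0 of 12 and 3 of 9 at 43 days. Counts called "in all 4 settings" held in the same direction as deposited, after quantile normalization, after median centring, and after median centring with the array set as a block.

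The first comparison asked how dKO hearts differed from HET hearts before disease was detectable, at 21 days on chow (n = 10 and 9). The largest rises were those of Mmp12, the macrophage elastase (2.59 ± 0.48, adjusted p = 1.75e-04), and Apod, a lipid-binding apolipoprotein (2.56 ± 0.37, adjusted p = 6.17e-07), which were 6.03-fold and 5.92-fold higher. Ccl2, a chemokine that attracts monocytes, rose by 2.01 ± 0.40 (adjusted p = 6.18e-04), and Lgals3, galectin-3 of macrophages, by 1.95 ± 0.36 (adjusted p = 1.75e-04). Lilr4b, a leukocyte receptor, rose by 1.55 ± 0.21, Ube2l6, an enzyme of ISG15 conjugation, by 1.66 ± 0.34, and Isg20, an interferon-induced exonuclease, by 1.49 ± 0.36. Falls that held in all 4 settings included those of Ddit4, an inhibitor of mTOR signalling (-1.86 ± 0.24, adjusted p = 1.31e-08), Map3k6, a stress kinase (-1.84 ± 0.40), and Fkbp5, a co-chaperone of the glucocorticoid receptor (-1.65 ± 0.35, adjusted p = 0.00248). Pheta1 (1.53 ± 0.40), Wee1 (-1.85 ± 0.46) and Lhx1 (-1.76 ± 0.47) passed as deposited but not in all 4 settings.

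By fixed gene list, 5 of 18 macrophage markers tested rose and 0 fell (7 and 0 adjusted over the list alone, 5 and 0 in all 4 settings). Cd68 rose by 1.12 ± 0.16, Mpeg1, encoding a pore-forming protein of macrophages, by 1.10 ± 0.18 and Tyrobp, a signalling adaptor, by 0.72 ± 0.17 (camera, adjusted p = 1.42e-09, and adjusted p = 0.0895 with an estimated correlation). For cholesterol efflux and targets of LXR, a sterol-sensing nuclear receptor, 2 of 10 genes tested rose and 0 fell (4 and 1 adjusted over the list alone, 2 and 0 in all 4 settings). These were Abca1, the cholesterol exporter (1.46 ± 0.17, adjusted p = 4.02e-10), and Srebf1, a regulator of lipid synthesis (1.16 ± 0.14), and the list was higher as a whole (camera, adjusted p = 1.42e-09). Erythroid markers were also higher (camera, adjusted p = 2.38e-06), and 2 of 5 of them tested rose and 0 fell (3 and 0 adjusted over the list alone, 2 and 0 in all 4 settings). Alas2, the erythroid enzyme that starts haem synthesis, rose by 1.23 ± 0.20 and the globin gene Hba-a1 by 0.58 ± 0.10. Glucocorticoid targets were lower (camera, adjusted p = 0.00473, and adjusted p = 0.369 with an estimated correlation), with 0 rising and 2 falling among 11 tested (0 and 3 adjusted over the list alone), namely Fkbp5 and Zbtb16, a transcription factor (-1.38 ± 0.22). Interferon-stimulated genes shifted up (camera, adjusted p = 0.0195, and adjusted p = 0.571 with an estimated correlation), with Rsad2, an antiviral enzyme, at 1.38 ± 0.35. Chemokines and cytokines (camera, adjusted p = 0.0154, and adjusted p = 0.386 with an estimated correlation), endothelial markers (camera, adjusted p = 0.00301, and adjusted p = 0.369 with an estimated correlation) and glycolysis genes (camera, adjusted p = 0.0117, and adjusted p = 0.571 with an estimated correlation) shifted up by the same test, and fatty acid oxidation genes down (camera, adjusted p = 0.0117, and adjusted p = 0.741 with an estimated correlation). After median centring camera no longer called the interferon (adjusted p = 0.107), chemokine (0.0615) and fatty acid oxidation lists (0.0773), nor the last with the array set as a block (0.0561). At this age 118 genes differed as deposited, 38 higher and 80 lower. Median centring gave 114 higher and 82 lower genes. In all 4 settings 37 genes were higher and 24 lower. With the array set as a block the count was 69, and within the larger and the smaller set it was 18 and 10.

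At 31 days (n = 10 and 10), when the design text places small infarcts in dKO mice, the largest rises were again led by Apod and Mmp12. Apod rose by 6.46 ± 0.36 (adjusted p = 6.77e-27), Mmp12 by 5.43 ± 0.46 (adjusted p = 6.56e-17) and Ccl8, a chemokine for monocytes, by 5.12 ± 0.36 (adjusted p = 5.16e-21). Lgals3 rose by 4.39 ± 0.35, Ccl2 by 3.72 ± 0.39, Isg20 by 3.57 ± 0.35, Sirpa, a myeloid receptor, by 3.46 ± 0.39 and Lilr4b by 3.11 ± 0.20. Falls that held in all 4 settings included those of Ptprv, a tyrosine phosphatase gene (-1.34 ± 0.37), the kinase gene Stk11 (-1.18 ± 0.26, adjusted p = 3.60e-04), Tubg2, a gamma-tubulin (-1.14 ± 0.40), Ces1d, a carboxylesterase (-1.12 ± 0.33, adjusted p = 0.00880), Aqp1, a water channel of vessels (-1.11 ± 0.16), and Ucp3, a mitochondrial uncoupling protein (-1.08 ± 0.28).

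In the macrophage list, 15 of 18 markers tested rose and 0 fell (17 and 0 adjusted over the list alone, 13 and 0 in all 4 settings), among them Ctss, the lysosomal protease cathepsin S (2.29 ± 0.19), Mpeg1 (2.33 ± 0.17) and Cd68 (2.13 ± 0.16), and the list was higher than other genes (camera, adjusted p = 4.06e-20). For the extracellular matrix, 17 of 29 genes tested rose and 0 fell (20 and 0 adjusted over the list alone, 15 and 0 in all 4 settings), with Lox, which cross-links collagen, at 2.73 ± 0.40 and Timp1, an inhibitor of matrix proteases, at 2.17 ± 0.30 (camera, adjusted p = 1.02e-07, and adjusted p = 0.128 with an estimated correlation). Meanwhile 9 of 13 cardiac stress and fetal genes tested rose and 0 fell (9 and 0 adjusted over the list alone, 8 and 0 in all 4 settings), including Sprr1a, a stress-induced protein of heart muscle (2.88 ± 0.33), and Ccn2, connective tissue growth factor (1.0 ± 0.19), with a shift of the whole list (camera, adjusted p = 1.85e-04, and adjusted p = 0.118 with an estimated correlation). Genes of energy supply were lower. In fatty acid oxidation, 0 of 27 genes tested rose and 16 fell (0 and 17 adjusted over the list alone, 0 and 16 in all 4 settings), such as Acadl, a dehydrogenase of long acyl chains (-0.77 ± 0.18), and Eci1 (-0.52 ± 0.09) (camera, adjusted p = 2.96e-14). In the citrate cycle and respiratory chain, 0 of 30 genes tested rose and 20 fell (0 and 22 adjusted over the list alone, 0 and 18 in all 4 settings), such as Ndufs3 of complex I (-0.46 ± 0.06) and Fh1, fumarate hydratase (-0.40 ± 0.08) (camera, adjusted p = 2.79e-19). Calcium handling genes (camera, adjusted p = 1.00e-04) and sarcomere genes (camera, adjusted p = 1.05e-04) were lower as lists, with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at -0.71 ± 0.13 and Myh6, the main heavy chain of adult mouse myosin, at -0.32 ± 0.07. Genes of cholesterol efflux and LXR (camera, adjusted p = 1.15e-10), chemokines and cytokines (camera, adjusted p = 2.38e-08) and erythroid markers (camera, adjusted p = 8.58e-06) were higher, and Hmox1, which breaks down haem, rose by 2.29 ± 0.17. In all, 1355 genes differed as deposited, 1135 higher and 220 lower. Centred on the array median, 672 were higher and 814 lower. Across all 4 settings 377 were higher and 209 lower. With the array set as a block 841 genes passed, and within the larger set 413, where only 4 HET hearts were left against 10 dKO hearts.

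At 43 days (n = 12 and 9), the stage of extensive infarcts, Apod was 112-fold higher in dKO hearts (6.81 ± 0.36, adjusted p = 7.59e-30) and Mmp12 rose by 6.48 ± 0.46 (adjusted p = 3.75e-22). The mean log2 signal of Mmp12 was 10.35 ± 0.43 (SD, n = 12) in dKO and 3.87 ± 1.48 (SD, n = 9) in HET hearts, where 1 of 9 arrays was at the floor. Lgals3 rose by 6.21 ± 0.34, Ccl8 by 6.05 ± 0.36, Lox by 5.92 ± 0.40, Ccl2 by 5.10 ± 0.38, Sprr1a by 4.80 ± 0.33 and Cd53, a leukocyte membrane protein, by 4.70 ± 0.31. Among the largest falls were those of Ces1d (-3.39 ± 0.33, adjusted p = 4.15e-15), Rxrg, a retinoid X receptor (-2.36 ± 0.27, adjusted p = 5.33e-12), Fbp2, the muscle fructose bisphosphatase (-2.34 ± 0.35), the glutathione transferases Gsta4 (-2.0 ± 0.25) and Mgst3 (-1.94 ± 0.17), and Dbp, a clock-controlled transcription factor (-1.88 ± 0.47).

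In the lists, 17 of 18 macrophage markers tested rose and 0 fell (17 and 0 adjusted over the list alone, 17 and 0 in all 4 settings), with Ctss at 4.40 ± 0.19, Mpeg1 at 3.85 ± 0.17 and Lyz2, lysozyme, at 3.01 ± 0.15 (camera, adjusted p = 4.00e-16). Of the matrix, 26 of 29 genes tested rose and 0 fell (26 and 0 adjusted over the list alone, 22 and 0 in all 4 settings). Col5a2 rose by 3.58 ± 0.16, Postn, periostin of activated fibroblasts, by 3.32 ± 0.18 (adjusted p = 1.77e-29) and Col3a1 by 2.63 ± 0.15 (camera, adjusted p = 1.21e-14). Likewise 13 of 13 cardiac stress and fetal genes tested rose and 0 fell (13 and 0 adjusted over the list alone, 10 and 0 in all 4 settings), with Ccn2 at 2.51 ± 0.19 and Uck2, a uridine kinase, at 2.16 ± 0.17 (camera, adjusted p = 6.41e-08). Within the citrate cycle and respiratory chain, 0 of 30 genes tested rose and 30 fell (0 and 30 adjusted over the list alone, 0 and 30 in all 4 settings). Cox7a1, the muscle form of a cytochrome oxidase subunit, fell by 1.66 ± 0.12, Ndufs3 by 0.88 ± 0.06 and Sdhb, of succinate dehydrogenase, by 0.77 ± 0.06 on the log2 scale (camera, adjusted p = 2.25e-29). Within fatty acid oxidation, 1 of 27 genes tested rose and 23 fell (1 and 23 adjusted over the list alone, 0 and 23 in all 4 settings), led by Ech1 (-1.59 ± 0.15), Hadh (-1.53 ± 0.14) and Eci1 (-1.23 ± 0.09) (camera, adjusted p = 1.06e-17). Calcium handling genes were lower too (camera, adjusted p = 1.25e-05), and 0 of 7 of them tested rose and 6 fell (0 and 6 adjusted over the list alone, 0 and 6 in all 4 settings), including Hrc (-1.77 ± 0.13) and Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.54 ± 0.10). Brown fat markers, of which 3 were tested, were lower as a list (camera, adjusted p = 0.00618) through Cox7a1 and Ppargc1a, a regulator of mitochondrial genes (-0.85 ± 0.26). Among sarcomere genes, 1 of 15 members tested rose and 7 fell (2 and 8 adjusted over the list alone, 1 and 7 in all 4 settings), with Tnni3, cardiac troponin I, at -0.56 ± 0.05, Myh6 at -0.56 ± 0.07 and Tpm1, a tropomyosin that rose, at 1.20 ± 0.14 (camera, adjusted p = 2.55e-04). At 43 days 2759 genes differed as deposited, 2101 higher and 658 lower. With each array centred on its median, 1202 were higher and 1569 lower. The direction held in all 4 settings for 1095 higher and 658 lower genes.

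**Figure D2:**
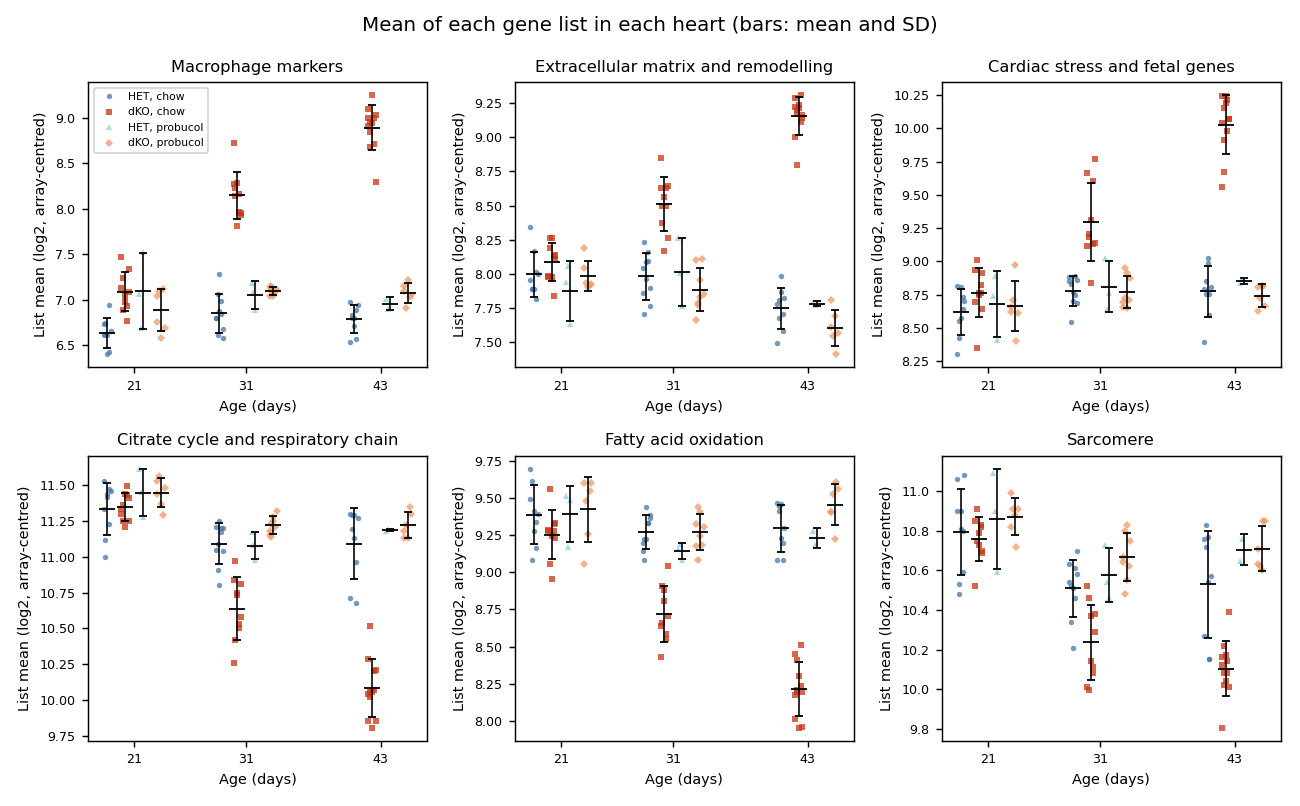
Mean log2 signal of 6 gene lists in each heart after centring on the array median (vertical axis) against age in days (horizontal axis), with bars for mean and SD and colours for genotype and diet. The macrophage, matrix and stress lists stand highest, and the citrate cycle, fatty acid oxidation and sarcomere lists lowest, in chow-fed dKO hearts at 43 days.

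Whether the genotype difference changed with age was tested as an interaction. From 21 to 31 days it grew most for Ccl8 (5.07 ± 0.52, adjusted p = 8.39e-12) and Apod (3.90 ± 0.52, adjusted p = 8.80e-08), and it became more negative for Tubg2 (-1.98 ± 0.57) and Stk11 (-1.54 ± 0.38). From 21 to 43 days it grew most for Lox (6.02 ± 0.57, adjusted p = 1.50e-14), Ccl8 (6.0 ± 0.52), Sprr1a (4.63 ± 0.47) and Cd53 (4.35 ± 0.45), and it became more negative for genes such as Ces1d (-2.75 ± 0.48, adjusted p = 2.38e-06), Rxrg (-2.53 ± 0.40) and Fbp2 (-2.02 ± 0.51). Between 21 and 31 days 821 genes differed as deposited, 795 higher and 26 lower. Median centring gave 358 higher and 328 lower genes. In all 4 settings 61 genes were higher and 14 lower. With the array set as a block the count fell to 142. Between 21 and 43 days 2211 genes differed as deposited, 1867 higher and 344 lower. Centred on the array median, 768 were higher and 1034 lower. Across all 4 settings 538 were higher and 342 lower. Of the 37 genes higher at 21 days in all 4 settings, 34 were also higher at 31 days against 2.46 expected of independent lists, and 35 at 43 days against 7.14. Of 24 lower genes, 5 were lower again at 31 days (0.884 expected) and 8 at 43 days (2.78 expected), where 1 was higher. As deposited, 11 of 80 lower genes stayed lower at 31 days and 15 were higher. Of 377 genes higher at 31 days 342 were higher at 43 days (72.8 expected), and of 209 lower genes 173 were lower again (24.2 expected). Different mice were compared at each age, so the groups compared share no arrays. The ages share the estimate of the spread of each gene, however, so the lists are not independent and the expected numbers are only a guide.

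In HET hearts on chow, 43 days were compared with 21 days to show change with age without detectable disease (n = 9 and 9). Acta1, skeletal alpha-actin of the fetal heart programme, rose 4.60-fold (2.20 ± 0.27, adjusted p = 1.39e-08). H2-Aa (2.05 ± 0.42, adjusted p = 3.84e-04) and H2-Ab1 (1.68 ± 0.37), the chains of a class II antigen-presenting molecule, rose with Cxcl14, a chemokine (1.75 ± 0.34), and Ccn5, a matrix-associated signalling protein (1.66 ± 0.35). Eln, elastin, fell to a 2.66-fold lower level (-1.41 ± 0.15, adjusted p = 1.54e-10), and Alas2 fell as well (-1.11 ± 0.20, adjusted p = 6.64e-05). The erythroid list was lower (camera, adjusted p = 1.07e-06), and 0 of 5 erythroid markers tested rose and 2 fell (1 and 2 adjusted over the list alone, 0 and 2 in all 4 settings). The matrix list was lower than other genes (camera, adjusted p = 2.73e-04, and adjusted p = 0.747 with an estimated correlation), while its median difference was 0.03 as deposited and -0.26 after median centring. In it 3 of 29 genes tested rose and 4 fell (3 and 4 adjusted over the list alone, 0 and 4 in all 4 settings). By camera 0 lists passed up and 5 down, and with an estimated correlation only 1, the erythroid list. With the array set as a block, the citrate cycle and respiratory chain (camera, adjusted p = 0.00368), sarcomere (0.017) and atrial lists (0.00262) were among the lower ones. Across this interval 1124 genes differed as deposited, 1096 higher and 28 lower. With each array centred on its median, 108 were higher and 204 lower. The direction held in all 4 settings for 91 higher and 28 lower genes. Without the 6 arrays with a high score on the first residual component, 3 of them in these 2 groups, the count as deposited was 510.

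Probucol was compared with chow in dKO hearts at each age. At 21 days (n = 6 and 10) the change was small. Tgfb1, the growth factor TGF-beta 1, fell by 2.25 ± 0.47 (adjusted p = 0.0123), Hmox1 by 1.0 ± 0.19 (adjusted p = 0.00637), Nes, the filament protein nestin, by 0.84 ± 0.19 and Tinagl1 by 0.82 ± 0.16 on the log2 scale. Alas2 passed as deposited (-0.91 ± 0.22, adjusted p = 0.0451) but not in all 4 settings, and the erythroid list was lower (camera, adjusted p = 1.39e-05). In total 10 genes differed as deposited, 0 higher and 10 lower. Median centring gave 2 higher and 16 lower genes. In all 4 settings 0 genes were higher and 6 lower. Within the larger array set limma called 0 genes, with 299 at an unadjusted p under 0.05. Replicate 2 of the dKO chow hearts, whose description in the labels gives another age, left 6 genes when it was taken out. Lists of endothelial markers (camera, adjusted p = 4.88e-05, and adjusted p = 0.166 with an estimated correlation) and macrophage markers (camera, adjusted p = 0.00125, and adjusted p = 0.841 with an estimated correlation) shifted down, and those of the citrate cycle and respiratory chain (camera, adjusted p = 8.30e-04, and adjusted p = 0.841 with an estimated correlation) and fatty acid oxidation (camera, adjusted p = 0.00775, and adjusted p = 0.850 with an estimated correlation) up. The citrate cycle list was lost after median centring (adjusted p = 0.0601) and the fatty acid oxidation list with the array set as a block (0.0581), where 6 of 10 chow and 1 of 6 probucol hearts were in the smaller set.

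At 31 days (n = 8 and 10), the largest falls with probucol were those of Mmp12 and Ccl8. Mmp12 fell by 4.32 ± 0.49 (adjusted p = 2.86e-11) and Ccl8 by 4.23 ± 0.38 (adjusted p = 2.90e-15) on the log2 scale, and others were Isg20 (-3.92 ± 0.37), Lgals3 (-3.73 ± 0.37), Tgfb1 (-3.22 ± 0.43), Tent5c (-2.98 ± 0.31) and Fcgr2b, an inhibitory receptor for antibodies (-2.83 ± 0.40). Rises included those of Adam28 (1.76 ± 0.41, adjusted p = 5.62e-04), Rbfox2, a splicing factor (1.17 ± 0.37), and Ces1d (1.0 ± 0.36, adjusted p = 0.0247). For macrophages, 0 of 18 markers tested rose and 15 fell (0 and 17 adjusted over the list alone, 0 and 13 in all 4 settings) (camera, adjusted p = 1.20e-13). Concerning the matrix, 0 of 29 genes tested rose and 19 fell (0 and 23 adjusted over the list alone, 0 and 15 in all 4 settings) (camera, adjusted p = 4.18e-10, and adjusted p = 0.0673 with an estimated correlation), with Postn at -1.53 ± 0.19. In addition 0 of 13 cardiac stress and fetal genes tested rose and 11 fell (0 and 11 adjusted over the list alone, 0 and 8 in all 4 settings), with Nppb, the natriuretic peptide of stretched ventricles, at -1.47 ± 0.23 (camera, adjusted p = 8.96e-05, and adjusted p = 0.0844 with an estimated correlation). In the citrate cycle and respiratory chain, 23 of 30 genes tested rose and 0 fell (25 and 0 adjusted over the list alone, 20 and 0 in all 4 settings), with Uqcrc2 of complex III at 0.57 ± 0.11 and Ndufs1 of complex I at 0.53 ± 0.10 (camera, adjusted p = 3.88e-26). Fatty acid oxidation (camera, adjusted p = 2.41e-12) and sarcomere genes (camera, adjusted p = 5.67e-08) were higher as lists, with Acadl at 0.73 ± 0.20 and Myh6 at 0.46 ± 0.08. In sum 1639 genes differed as deposited, 121 higher and 1518 lower. Centred on the array median, 717 were higher and 620 lower. Across all 4 settings 113 were higher and 608 lower.

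At 43 days (n = 6 and 12) Mmp12 and Ccl8 led the falls again and Ces1d the rises. Mmp12 fell by 5.83 ± 0.52 (adjusted p = 9.82e-17), and other falls were those of Ccl8 (-5.24 ± 0.40), Lox (-5.08 ± 0.45) and Sprr1a (-4.28 ± 0.37). Serpina3n, an acute-phase protease inhibitor, fell by 4.29 ± 0.38 on that scale. Ces1d rose 10.9-fold (3.45 ± 0.37, adjusted p = 5.97e-13), Fbp2 by 2.58 ± 0.40 (adjusted p = 6.70e-08), Gsta4 by 2.38 ± 0.28, Rxrg by 2.25 ± 0.31 and Inmt, a methyltransferase, by 1.96 ± 0.28. In the citrate cycle and respiratory chain, 30 of 30 genes tested rose and 0 fell (30 and 0 adjusted over the list alone, 30 and 0 in all 4 settings), with Cox7a1 at 1.46 ± 0.13 and Sdhb at 0.71 ± 0.06 (camera, adjusted p = 4.96e-38). For energy supply from fat, 21 of 27 fatty acid oxidation genes tested rose and 1 fell (21 and 1 adjusted over the list alone, 21 and 0 in all 4 settings) (camera, adjusted p = 9.94e-23), with Etfa, an electron carrier, at 1.03 ± 0.11. In the macrophage list, 0 of 18 macrophage markers tested rose and 17 fell (0 and 17 adjusted over the list alone, 0 and 17 in all 4 settings) (camera, adjusted p = 4.14e-15). For the matrix list, 0 of 29 genes tested rose and 27 fell (0 and 27 adjusted over the list alone, 0 and 24 in all 4 settings), with Col5a2 at -3.54 ± 0.18 and Postn at -3.35 ± 0.20 (camera, adjusted p = 4.56e-19). Furthermore 0 of 13 cardiac stress and fetal genes tested rose and 13 fell (0 and 13 adjusted over the list alone, 0 and 11 in all 4 settings) (camera, adjusted p = 5.32e-09). Sarcomere genes were higher as a list (camera, adjusted p = 1.67e-06), and 10 of 15 of them tested rose and 1 fell (10 and 1 adjusted over the list alone, 10 and 1 in all 4 settings), with Myh6 at 0.76 ± 0.08 and Tnni3 at 0.73 ± 0.05, and calcium handling genes were higher too (camera, adjusted p = 6.68e-06). The 3 brown fat markers tested were higher as a list (camera, adjusted p = 0.00265) through Cox7a1 and Ppargc1a (1.26 ± 0.30), while Cidea differed by 0.056 ± 0.16 (adjusted p = 0.808). At this age 2587 genes differed as deposited, 466 higher and 2121 lower. With each array centred on its median, 1356 were higher and 963 lower. The direction held in all 4 settings for 466 higher and 957 lower genes.

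**Figure D3:**
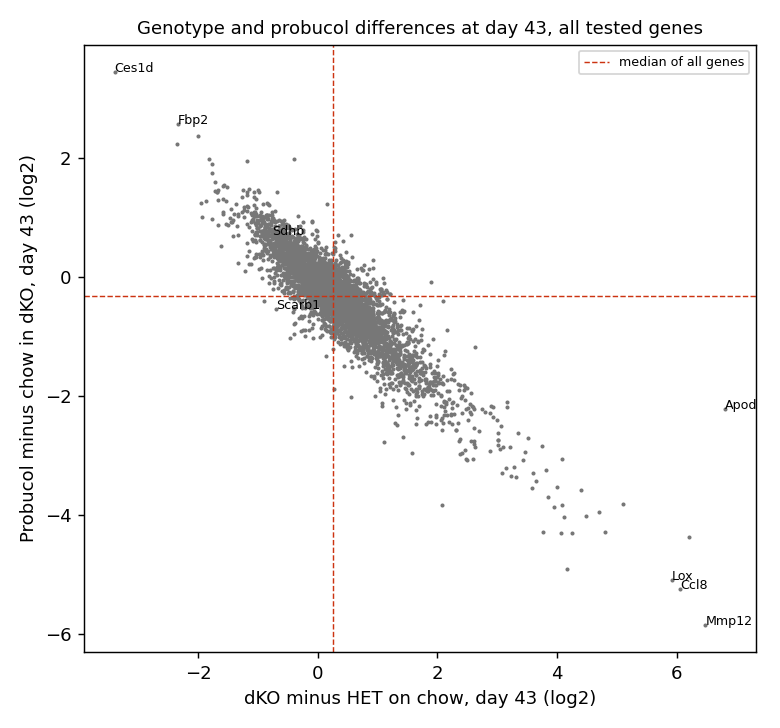
Log2 difference with probucol in dKO hearts (vertical axis) against the log2 difference between dKO and HET hearts on chow (horizontal axis) at 43 days, with a point per tested gene and dashed lines at the median of all genes. The points run from upper left, with Ces1d and Fbp2, to lower right, with Mmp12, Ccl8 and Lox.

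The genotype and probucol differences were set against each other gene by gene. At 43 days they were inversely related across genes, with a Pearson correlation of -0.90 (Spearman -0.85), and at 31 days of -0.71 (-0.64), where genes are not independent replicates. Both comparisons use the chow-fed dKO hearts, and unchanged groups simulated against the same hearts gave -0.383 and -0.475. The covariance at 43 days was -0.455 against -0.0183 simulated, and at 31 days -0.152 against -0.0219. With the dKO chow hearts split between the comparisons, the correlation was -0.863 and -0.847 at 43 days and -0.625 and -0.576 at 31 days. After median centring, 824 of 1202 genes higher and 1137 of 1569 genes lower in dKO hearts at 43 days moved the other way with probucol, against 204 and 375 expected of independent lists. With split controls it was 660 of 980 and 901 of 1322 for the odd-numbered dKO chow hearts, and 660 of 996 and 890 of 1334 for the even-numbered. At 31 days the overlaps were 328 of 672 and 453 of 814 (73.5 and 103 expected). With split controls at that age they were 180 of 504 (26.2 expected) and 188 of 601 (34.6 expected) for the odd-numbered hearts, and 181 of 330 (29.3 expected) and 204 of 412 (40.3 expected) for the even-numbered. Among 833 genes at least 2-fold apart between genotypes at 43 days, the median share of the difference left with probucol was 6.42%. Its 95% bootstrap interval was -3.59 to 13.5. The share was 9.49% (3.75 to 14.1) after median centring and 9.37% (4.16 to 12.6) after quantile normalization, so on those scales a small part remained. The genes were chosen on some of the dKO chow hearts and measured on the others. The HET chow hearts were the same in both steps, so the share is not fully free of the choice of genes. As deposited the share was 4.53% for genes higher and 17.3% for genes lower in dKO hearts, against 12.7% and 5.01% after median centring. With HET probucol hearts as the reference of the remaining difference it was 0.0245%.

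In HET hearts few genes passed the threshold with probucol, which 3, 3 and 2 mice received. By Xist above Eif2s3y, 3, 1 and 0 of these mice were read as female, against 5 of 9, 4 of 10 and 4 of 9 on chow. Apod recurred at all ages, higher by 2.76 ± 0.54 (adjusted p = 0.00286) at 21 days, 3.19 ± 0.53 (adjusted p = 1.68e-04) at 31 days and 3.33 ± 0.63 (adjusted p = 0.00263) at 43 days. It stayed past the threshold at 31 days whichever treated mouse was left out, while at 21 days it was 2.11 (adjusted p = 0.150) without HET probucol replicate 3 and at 43 days 2.98 (adjusted p = 0.0736) without replicate 1. Apod of the 3 treated hearts at 31 days was 6.65 to 6.85, and all 3 were in the larger array set. HET chow hearts of that set had 3.77 to 5.35, against 2.08 to 5.19 for the 6 of 10 in the smaller set. At 21 days Igtp, an interferon-induced GTPase (2.52 ± 0.56, adjusted p = 0.0180), and the class I antigen-presentation genes H2-K2 (2.45 ± 0.59), H2-Q5 (2.35 ± 0.57) and H2-Q4 (1.75 ± 0.41) passed. These calls rested on HET probucol replicate 3, without which the values were 0.11 (adjusted p = 0.946), 1.26 (adjusted p = 0.476), 1.20 (adjusted p = 0.485) and 0.43 (adjusted p = 0.742). H2-K2 was also lost without replicate 1 (2.39, adjusted p = 0.105). Interferon-stimulated genes (camera, adjusted p = 4.69e-07, and adjusted p = 0.145 with an estimated correlation) and macrophage markers (camera, adjusted p = 3.26e-06, and adjusted p = 0.564 with an estimated correlation) shifted up as lists. These shifts also rested on replicate 3, without which the adjusted p was 0.986 and 0.173. At 31 days Cfp, properdin of the complement system, rose (1.26 ± 0.29, adjusted p = 0.0160) and Fmnl1, a formin, fell (-2.70 ± 0.52, adjusted p = 0.00202). Cfp was lost without HET probucol replicate 1 (1.22, adjusted p = 0.116) or 3 (1.15, adjusted p = 0.228), and Fmnl1 without replicate 2 (-2.47, adjusted p = 0.0556). At 43 days Tpm2, a tropomyosin, was lower with probucol (-1.86 ± 0.29, adjusted p = 5.67e-05), as was Gphn, gephyrin (-2.09 ± 0.44), which rested on replicate 2 (-0.16, adjusted p = 1.0 without it). The counts were 22 genes at 21 days (13 higher, 9 lower), 33 at 31 days (8 and 25) and 8 at 43 days (1 and 7), and after median centring 27 and 6, 38 and 78, and 1 and 11. At 21 days the count was 7, all lower, without HET probucol replicate 3, and 34 and 49 without replicates 1 and 2. At 31 days it was 19, 11 and 4 without replicates 1, 2 and 3, and at 43 days 49 without replicate 1. Fitted on the groups compared alone, limma called 0 genes at 21 and 43 days, with 335 and 377 at an unadjusted p under 0.05.

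Between dKO and HET hearts on probucol, limma called 0 genes at 31 days (n = 8 and 3), and also 0 after quantile normalization and after median centring. As deposited, 231 of 5672 genes had an unadjusted p under 0.05, fewer than the 5% expected by chance. Genes are not independent, and recovery was not simulated for this comparison, so the lack of calls does not show that the genotypes were alike. At 43 days (n = 6 and 2) 1 gene passed, Tpm2 (2.01 ± 0.31, adjusted p = 2.21e-05). After quantile normalization 13 passed (10 higher, 3 lower) and after median centring 3 (2 and 1), and the counts were 26 and 5 without HET probucol replicate 1 or 2. Scarb1 itself differed by -1.04 ± 0.25 (adjusted p = 0.490) and -1.26 ± 0.30 (adjusted p = 0.117), and after median centring its adjusted p was 0.196 and 0.0125. By camera 2 lists passed at 31 days, the matrix list down (camera, adjusted p = 0.0335, and adjusted p = 0.935 with an estimated correlation) and the citrate cycle and respiratory chain up (camera, adjusted p = 0.0335, and adjusted p = 0.935 with an estimated correlation), the latter not after quantile normalization (adjusted p = 0.551). At 43 days 7 passed, among them the matrix list down (camera, adjusted p = 0.0191, and adjusted p = 0.803 with an estimated correlation) and heat shock genes up (camera, adjusted p = 0.0191, and adjusted p = 0.803 with an estimated correlation). With an estimated correlation camera called 0 and 0 lists at the 2 ages, and 0 and 0 lists had an unadjusted p under 0.05. Without replicate 1 or 2 of the HET probucol hearts at 43 days the matrix list had an adjusted p of 0.119 and 0.104. The probucol difference was then compared between genotypes as an interaction. It was more negative in dKO hearts for Apod (-5.47 ± 0.65, adjusted p = 9.46e-10), Ccl8 (-5.30 ± 0.66) and Mmp12 (-5.04 ± 0.84) at 31 days, and for Mmp12 (-7.15 ± 0.96, adjusted p = 1.21e-08), Ccl8 (-6.70 ± 0.75), Lox (-5.37 ± 0.84) and Serpina3n (-5.05 ± 0.71) at 43 days. It was more positive at 43 days for Ces1d (3.71 ± 0.69, adjusted p = 2.58e-05) and Fbp2 (2.91 ± 0.74), which without HET probucol replicate 2 had 2.66 (adjusted p = 0.0537). At 31 days 527 genes differed as deposited, 39 higher and 488 lower. Median centring gave 228 higher and 185 lower genes. In all 4 settings 37 genes were higher and 123 lower. At 43 days 1036 genes differed as deposited, 309 higher and 727 lower. Centred on the array median, 729 were higher and 474 lower. Across all 4 settings 309 were higher and 448 lower. The count as deposited at 31 days was 251 and 255 without HET probucol replicate 2 or 3, and 297 with the array set as a block. At 43 days it was 652 and 581 without HET probucol replicate 1 or 2.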

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

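The random splits of the arrays were planned, while the tests of the 3 patterns weighed here, including those with the array sets, were chosen after the results had been seen. Single hearts stood far from the rest of their group in 6 of 96 groups of values tested, where chance gives about 1 in 20. Ccl8 had a log2 signal of 6.36 in dKO chow replicate 6 at 21 days, against 3.37 to 4.40 in the other hearts of the group. It was 5.90 in dKO probucol replicate 4 at 21 days, against 3.33 to 3.78. Fkbp5 was 5.20 in HET chow replicate 2 at 21 days, an array with a high score on the first residual component, against 6.83 to 7.76. HET chow replicate 5 at 31 days had the highest Sdhb, 11.80 against 11.36 to 11.59, and the highest Acadm, 11.51 against 10.28 to 10.93. Scarb1 was 5.35 in dKO probucol replicate 3 at 21 days, against 6.14 to 6.39.

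Groups differed in their response by the tests of the difference itself. The genotype difference on chow changed from 21 to 31 days for 821 genes as deposited, 142 with the array set as a block and 75 in all 4 settings, and from 21 to 43 days for 2211. The probucol effect differed between genotypes for 527 genes at 31 days, 297 with the block and 160 in all 4 settings, and for 1036 at 43 days. The count at 31 days was 251 and 255 without HET probucol replicate 2 or 3, and at 43 days 652 and 581 without replicate 1 or 2. Probe sets outside the gene tests also differed between genotypes. After centring on the array median, 1259 of 4969 dim probe sets differed between genotypes on chow at 43 days, 305 higher and 954 lower, against 18 at 21 days. As deposited it was 491, 407 higher and 84 lower, against 22. Centring lowers values at the floor in brighter arrays by construction. The mean of the array medians at 43 days was 58.98 in dKO and 47.34 in HET chow hearts. The 954 lower probe sets can therefore not be read as falls, and the direction of dim probe sets depends on the scaling. Of 748 probe sets without a single symbol 318 differed at 43 days, 144 higher and 174 lower, against 36 at 21 days, all after the same centring. As deposited it was 312, 254 higher and 58 lower, against 22.

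The lower respiratory chain and fatty acid oxidation genes in chow-fed dKO hearts at 43 days were weighed first. If less heart muscle RNA in whole-heart RNA were the whole cause, sarcomere genes should have fallen by as much. The 57 mitochondrial genes fell by 0.62 more than the 15 sarcomere genes on the log2 scale (SE 0.06). Sarcomere genes moved apart, however, with Tpm1 rising and Tnni3 and Myh6 falling. Their mean is thus no clean measure of the muscle share, and the test cannot decide this. As deposited, where the median gene was higher in dKO hearts, the mitochondrial mean still fell by 0.72 (SE 0.05), which argues against scaling as its source, and the sarcomere mean differed by -0.10 (SE 0.06). Of brown fat markers that heart muscle does not share, only Cidea was bright enough to be tested, at -0.11 (SE 0.15), while 2 dim probe sets of Ucp1 had mean log2 signals of 4.61 and 4.19 in HET and 3.75 and 4.04 in dKO hearts, and Dio2, also below the filter, was higher in dKO hearts (6.13 against 4.07). A smaller share of muscle RNA, brown fat RNA, a lower level within the muscle cells, and changes in both the muscle share and the level per cell stay open.

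Glucocorticoid targets were lower in dKO hearts at 21 days, with a difference of -0.42 (SE 0.13) for the mean of the list after median centring, though the list test passed only at the preset correlation (adjusted p = 0.00473, and 0.369 with an estimated one). The array sets were unevenly spread over the groups, yet within the larger set, with 4 dKO and 7 HET hearts, the difference was -0.42 (SE 0.13), which argues against the sets as the whole cause. Within the smaller set, with 6 and 2 hearts, it was -0.18 (SE 0.44). A different time of day of collection could lower such genes, and a score of clock genes differed by 0.054 (SE 0.38), too wide a spread to decide without collection times. Stress at handling and the genotype itself also stay open and were not tested.

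The genes that differed between genotypes at 31 days were the third pattern, since the smaller array set held 6 of 10 HET and 0 of 10 dKO hearts. If the sets made the whole pattern, most of the calls should have been lost with the set as a block, and 793 of 1355 stayed past the threshold in the same direction. The calls lost with the block may depend on the set. Differences within the larger set correlated at 0.877 with those over all arrays and 1313 of 1355 kept their sign, but 14 of the 20 arrays are shared, so this value decides nothing.

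Splits of the same arrays into other groups, 100 for each comparison with the real one included, showed how many genes other groupings give. For genotype on chow only the real split reached the count at 21 days (118, at most 116 in another) and at 31 days (1355, at most 355). The splits left aside the array set, which was unevenly spread over these groups, so they alone do not settle these counts. At 43 days chance was excluded (2759, at most 1344), and the count with the set as a block was 2619. The split with 116 genes put 7 and 1 arrays of the smaller set in its groups, against 6 and 2 in the real ones, and with the set as a block the count at 21 days was 69. Chance was excluded for probucol in dKO hearts at 31 days (1639, at most 975) and 43 days (2587, at most 1608), with 1 split each time. For the change of the genotype difference to 43 days only the real split reached 2211, at most 30 in another. Splits for such changes shuffled genotype within each age. They stand for no genotype difference at any age, not for a constant one, so they do not settle this count. For the change to 31 days 1 split reached 821, at most 464 in another, but the splits left the array set aside, and the count was 142 with the set as a block, 137 with block and median centring and 29 within the larger set. For the difference of the probucol effect at 31 days 1 split reached 527, at most 292 in another, which put 3 arrays of the smaller set in the HET probucol group, where the real one had 0. With the set as a block the count was 297, within the larger set 175, and without HET probucol replicate 2 or 3 it was 251 and 255, so the splits alone do not settle this count. For probucol in dKO hearts at 21 days only the real split reached 10, at most 5 in another. The smaller set held 6 of 10 chow and 1 of 6 probucol hearts. The count was 8 with the block and 0 within the larger set, where limma had 299 genes at an unadjusted p under 0.05. The splits alone do not settle this count. For age in HET hearts 2 of the 100 splits reached 1124, the highest other with 1125, so the splits do not settle this count. That split put all 3 arrays with a high score on the first residual component and 4 of 5 arrays of the smaller set in 1 group, and the count was 510 without those high-scoring arrays and 319 with the set as a block after median centring. Chance was not excluded for probucol in HET hearts at 21 days (22 genes, 7 splits, at most 120) and 31 days (33 genes, 5 splits, at most 96). Splits with several times the real count point to structure among the arrays. The one with 96 genes at 31 days put 3 arrays of the smaller set in the group of 3, where the real group had 0. With the set as a block the real count was 33, and within the larger set it was 16. For genotype on probucol at 31 days all 100 splits gave at least the 0 genes limma called, at most 30. Of 5672 genes, 231 had an unadjusted p under 0.05, fewer than the 5% expected by chance, though genes are not independent. This does not show that the genotypes were alike on probucol. No splits were run for comparisons with the group of 2 hearts.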

How the results depend on the processing

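The alternatives with array sets, high-scoring arrays, the Eif2s3y and actin covariates and lists without single hearts were chosen after the results had been seen, and the others were planned. Of 365 alternative values for counts, shares and list tests, 271 stayed within 1.5 times the value as reported or within its spread, and 94 moved. For counts only the total was compared, so a count could stay while its balance of higher and lower genes changed. Genotype at 31 days had 1355 genes both as deposited (1135 higher, 220 lower) and after quantile normalization (624 higher, 731 lower). For the values that moved, the cause was not tested unless the construction of the alternative gives it. Counts of genes past the threshold that moved are listed first. There, genotype stands for dKO against HET on chow, and genotype by age and genotype by probucol for the interactions. No detection calls were used, and genes near the floor limit what can be seen.

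The count of genes follows for each setting. After quantile normalization it was 399 for genotype by age to 31 days, 281 for age in HET, 19 for probucol in dKO at 21 days and 148 for probucol in HET at 31 days. It was 30 for probucol in HET at 43 days and 13 for genotype on probucol at 43 days. After median centring it was 196 for genotype at 21 days, 312 for age in HET, 18 for probucol in dKO at 21 days and 116 for probucol in HET at 31 days. It was 3 for genotype on probucol at 43 days. With the floor at the 30th percentile it was 77 for genotype at 21 days and 5 for probucol in HET at 43 days. Without a filter on dim probe sets it was 5 for probucol in HET at 43 days. With only the upper 40% of probe sets, which leaves fewer genes, it was 61 for genotype at 21 days, 461 for genotype by age to 31 days and 2 for genotype on probucol at 43 days. Fitted on the groups compared alone, with fewer arrays, it was 55 for genotype at 21 days, 502 for age in HET, 0 for probucol in HET at 21 days and 19 for probucol in HET at 31 days. It was 0 for probucol in HET at 43 days and 4 for genotype on probucol at 43 days. With array weights it was 196 for genotype at 21 days, 2063 for genotype at 31 days, 1514 for genotype by age to 31 days and 687 for age in HET. It was 54 for probucol in dKO at 21 days, 443 for probucol in HET at 31 days, 27 for probucol in HET at 43 days and 2 for genotype on probucol at 31 days. It was 7 for genotype on probucol at 43 days, 1379 for genotype by probucol at 31 days and 1630 for genotype by probucol at 43 days. With the Gapdh ratio as a covariate it was 18 for probucol in dKO at 21 days and 5 for probucol in HET at 43 days. With a minimum of 1.5-fold, stricter by construction, it was 790 for genotype at 31 days, 1833 for genotype at 43 days, 475 for age in HET and 957 for probucol in dKO at 31 days. Where the groups alone gave 0, 335 genes at 21 days and 377 at 43 days had an unadjusted p under 0.05 in limma.

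With the array set as a block it was 69 for genotype at 21 days, 841 for genotype at 31 days, 142 for genotype by age to 31 days and 2 for genotype on probucol at 43 days. It was 297 for genotype by probucol at 31 days. With that block and median centring it was 137 for genotype by age to 31 days, 319 for age in HET, 35 for probucol in HET at 21 days and 15 for probucol in HET at 43 days. It was 3 for genotype on probucol at 43 days and 304 for genotype by probucol at 31 days. Within the larger array set, with fewer arrays, it was 18 for genotype at 21 days, 413 for genotype at 31 days, 29 for genotype by age to 31 days and 1114 for genotype by age to 43 days. It was 0 for probucol in dKO at 21 days, 40 for probucol in HET at 21 days, 16 for probucol in HET at 31 days and 3 for genotype on probucol at 43 days. It was 175 for genotype by probucol at 31 days. Within the smaller set it was 10 for genotype at 21 days and 27 for age in HET. In all 4 settings together, stricter by construction, it was 61 for genotype at 21 days, 586 for genotype at 31 days, 1753 for genotype at 43 days and 75 for genotype by age to 31 days. It was 880 for genotype by age to 43 days, 119 for age in HET, 6 for probucol in dKO at 21 days and 721 for probucol in dKO at 31 days. It was 1423 for probucol in dKO at 43 days and 160 for genotype by probucol at 31 days. Without the 6 arrays with a high residual score it was 510 for age in HET, 19 for probucol in dKO at 21 days and 59 for probucol in HET at 31 days. With the covariate of Eif2s3y minus Xist it was 5 for probucol in HET at 43 days. Where the larger set gave 0, limma had 299 genes at an unadjusted p under 0.05. With 1 replicate left out at a time, it was 6 for probucol in dKO at 21 days, 7 to 49 for probucol in HET at 21 days, 4 to 19 for probucol in HET at 31 days, 251 to 370 for genotype by probucol at 31 days, 8 to 49 for probucol in HET at 43 days, 5 to 26 for genotype on probucol at 43 days and 581 to 652 for genotype by probucol at 43 days. At 43 days this leaves 1 HET probucol heart, which is assumed to vary like the other groups.

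No pairing of hearts by replicate number was found. Hearts with the same number had mean residual correlations of -0.07 to 0.06 between groups, at most 2 hearts of any comparison correlated best with their own number, which was 2 of 3 for probucol in HET at 21 days and genotype on probucol at 31 days, and nothing in the labels links the numbers. With the number as a block, the count was 67 for probucol in HET at 31 days and 4 at 43 days, and the other counts stayed within 1.5 times. The block left past the threshold 115 of 118 genes for genotype at 21 days, 1338 of 1355 at 31 days and 2485 of 2759 at 43 days, and 2117 of 2587 for probucol in dKO at 43 days. For probucol in HET it left 14 of 22 at 21 days, 28 of 33 at 31 days and 4 of 8 at 43 days.

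The share of the genotype difference left with probucol was 6.42% as reported (95% bootstrap interval -3.59 to 13.5). It was 9.37% (4.16 to 12.6) after quantile normalization and 9.49% (3.75 to 14.1) after median centring. With HET probucol hearts as the reference it was 0.0245%. The number of pairs of list and contrast past the threshold by camera, of 544, was 139 as reported, 68 with an estimated correlation, 136 after quantile normalization, 145 after median centring, 139 with the array set as a block and 131 to 144 without single HET probucol hearts. With the actin ratio as a covariate no count moved. Of 919 alternative values for single genes, 862 kept direction and side of the threshold, 42 lost the threshold, 3 gained it and 12 turned sign. In another probe set of the gene, the difference was 0.071 for Fcgbp at 31 days, and at 43 days -0.37 for Lep, -0.43 for Myh7 and 0.79 for Myl4, all between genotypes. With probucol in dKO hearts it was 0.20 for Fth1 and -1.63 for Lig1 at 31 days, and -0.21 for Hspd1, 0.10 for Lep, 0.30 for Myh7 and -0.65 for Myl4 at 43 days. Nppa with probucol at 31 days was 0.012 after median centring and 0.00254 with the array set as a block too. The planned covariate of Ddx3y minus Xist was not run, and fits within the smaller array set were made only where each group kept at least 2 hearts.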

Other observations

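The lists described here were fixed beforehand, while the choice of which to describe and the correlations within groups came after the results had been seen. At 43 days on chow, changes went beyond macrophage, matrix and energy supply genes. Among cell cycle genes, 12 of 16 members tested rose and 0 fell (12 and 0 adjusted over the list alone, 11 and 0 in all 4 settings), with Cdk1, a kinase of cell division, at 2.31 ± 0.41 and Nusap1, a spindle protein, at 2.36 ± 0.36 (camera, adjusted p = 0.0574, and adjusted p = 0.478 with an estimated correlation). Of the chemokines, 9 of 10 members tested rose and 0 fell (9 and 0 adjusted over the list alone, 7 and 0 in all 4 settings), and Ccl7 stood at 3.47 ± 0.36 (camera, adjusted p = 5.23e-05). Neutrophil genes included S100a9 at 4.12 ± 0.41 and S100a8 at 3.43 ± 0.33, which form calprotectin, and 5 of 7 neutrophil markers tested rose and 0 fell (5 and 0 adjusted over the list alone, 3 and 0 in all 4 settings) (camera, adjusted p = 0.155, and adjusted p = 0.478 with an estimated correlation). Complement genes were higher (camera, adjusted p = 0.00284, and adjusted p = 0.0760 with an estimated correlation), with C3ar1, a receptor of myeloid cells, at 2.69 ± 0.18 and Cfp at 2.88 ± 0.19. For cholesterol efflux, 10 of 10 genes tested rose and 0 fell (10 and 0 adjusted over the list alone, 8 and 0 in all 4 settings), with Abca1 at 2.63 ± 0.16 and Pltp, which transfers phospholipids, at 2.04 ± 0.13 (camera, adjusted p = 5.90e-06). The interferon-stimulated list did not pass (camera, adjusted p = 0.179, and adjusted p = 0.539 with an estimated correlation), though its member Rsad2 stood at 3.81 ± 0.34.

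Members of several lists moved apart at 43 days. In glycolysis, 5 of 15 genes tested rose and 7 fell (5 and 7 adjusted over the list alone, 3 and 7 in all 4 settings), with the muscle forms Pfkm at -1.11 ± 0.11 and Pgam2 at -0.90 ± 0.10 and the widely expressed Pgam1 at 1.74 ± 0.17 (camera, adjusted p = 0.0144, and adjusted p = 0.423 with an estimated correlation). For oxidative stress and NRF2 targets, 13 of 19 genes tested rose and 4 fell (13 and 4 adjusted over the list alone, 10 and 4 in all 4 settings), with Hmox1 at 2.56 ± 0.16 and Gsta4 at -2.0 ± 0.25 (camera, adjusted p = 0.194, and adjusted p = 0.539 with an estimated correlation). Of heat shock genes, 5 of 10 members tested rose and 2 fell (5 and 2 adjusted over the list alone, 3 and 2 in all 4 settings), and the list did not pass (camera, adjusted p = 0.854, and adjusted p = 0.917 with an estimated correlation). Hspa1b, an inducible chaperone, stood at 1.92 ± 0.33, and the mitochondrial chaperones Hspd1 at -0.62 ± 0.16 and Hspe1 at -0.42 ± 0.11. Of the clock, 2 of 11 genes tested rose and 4 fell (2 and 4 adjusted over the list alone, 2 and 4 in all 4 settings), and the list did not pass (camera, adjusted p = 0.195, and adjusted p = 0.478 with an estimated correlation). Arntl, an activator of the clock, stood at 1.45 ± 0.39 and Dbp, one of its targets, at -1.88 ± 0.47, and with probucol Dbp was at 1.28 ± 0.54 (adjusted p = 0.0423) in dKO hearts. Glucocorticoid targets, lower at 21 days by the preset test only, had 6 rises and 2 falls among 11 at 43 days, with Cdkn1a, a cell cycle inhibitor, at 1.54 ± 0.30 and Zbtb16 at -1.58 ± 0.21 (camera, adjusted p = 0.791, and adjusted p = 0.892 with an estimated correlation).

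Among erythroid markers at 43 days on chow, 3 of 5 members tested rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 0 in all 4 settings) (camera, adjusted p = 0.00483, and adjusted p = 0.0595 with an estimated correlation). Alas2 was higher at all ages, at 1.23 ± 0.20, 2.94 ± 0.19 and 3.94 ± 0.19 in dKO against HET hearts at 21, 31 and 43 days. Slc4a1, the anion exchanger of red cells, was at 2.23 ± 0.27 at 43 days, where with probucol Alas2 was at -3.86 ± 0.21 and Slc4a1 at -2.31 ± 0.30 in dKO hearts. Whole hearts hold blood, and no blood counts were used here. At 31 and 43 days Apod moved in opposite directions with probucol in the 2 genotypes, while at 21 days it was 6.76 ± 0.71 (SD, n = 10) on chow and 8.11 ± 1.04 (SD, n = 6) with probucol in dKO hearts, higher by 1.35 ± 0.42 (adjusted p = 0.212), not past the threshold. At 43 days its mean log2 signal was 4.32 ± 1.31 (SD, n = 9) on chow and 7.65 ± 0.50 (SD, n = 2) with probucol in HET hearts, a difference that missed the threshold without HET probucol replicate 1 (2.98, adjusted p = 0.0736). In dKO hearts it was 11.13 ± 0.20 (SD, n = 12) on chow and 8.92 ± 0.47 (SD, n = 6) with probucol, and the interaction was -5.54 ± 0.75 (adjusted p = 1.24e-08).

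Within chow-fed dKO hearts of 1 age, the macrophage list mean was compared with the matrix and mitochondrial list means, in 6 relations. None passed after adjustment over the 6. The strongest was with the matrix list at 31 days (n = 10), with Pearson's r = 0.717 (2-sided permutation p = 0.0193, adjusted p = 0.116) and Spearman's rho = 0.588 (permutation p = 0.0808, adjusted p = 0.162). It rested on those hearts that lay farthest from the median, as r was 0.178 without the 2 hearts with the most distant macrophage values. At 43 days (n = 12) the relation with the mitochondrial lists had r = -0.393 (permutation p = 0.207) and rho = -0.552 (permutation p = 0.0656).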
